A study of Mus musculus with 12 samples.

How the data were processed

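Total RNA from 12 samples of mouse primary NRASG12V, MLL-AF9 acute myeloid leukaemia cells of an FVB/n by C57BL/6J F1 background was sequenced, 3 libraries for each of DMSO, PD325901 (20 µM), RAD001 (26 µM) and GDC0941 (20 µM), after 24 h. The labels number the libraries of each group 1 to 3 and do not say whether a number stands for a culture, an animal or a day.

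The authors deposited 1 table of FPKM values with a symbol for each of 23234 genes and a column for each library. The FPKM values were made by the authors with TopHat2 2.0.4 and Cuffdiff on the mm9 genome build, per the submitters' processing notes. The annotation, the Cuffdiff version and the normalization between libraries are not given in the sources used here. The values are not whole numbers, hold many exact zeros and add up to 462335 to 587581 FPKM per library. No positions are given, since the table holds symbols only.

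Genes with a mean of at least 1 FPKM over the 12 libraries (10305 genes) were analysed as log2(FPKM + 1). With R 4.3.3 and limma 3.58.1, 1 linear model with 4 group means was fitted to all 12 libraries (8 residual degrees of freedom), followed by eBayes with a trend. Each inhibitor was compared with DMSO and the inhibitors with each other, two-sided, with p adjusted by the Benjamini-Hochberg method within each comparison and a threshold of 0.05. SD values are those of FPKM within a group, and SE values are those of the limma fit. Adjusting over the list alone means that the Benjamini-Hochberg method was applied to the members of that list only.

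From textbook knowledge 29 gene lists, some with shared members, were fixed before the data were examined. The 24 lists with at least 5 members tested were tested with limma camera at a preset inter-gene correlation of 0.01, and p was adjusted over 72 tests (24 lists and 3 comparisons with DMSO). The lists cover ERK output, FOXO targets, sterol and fatty acid synthesis, ATF4 and amino acid response, glycolysis and hypoxia, lysosome and TFEB targets, ribosome biogenesis, S phase, mitosis, the MLL fusion and HoxA program, stem and progenitor cells, monocytes and macrophages, primary granules, neutrophil maturation, antigen presentation, NF-kB targets with cytokines and chemokines, interferon response, STAT5 and cytokine receptors, p53 targets, the BCL2 family, ER stress, the Ras pathway with the drug targets, and mast cells with basophils and eosinophils. Lists for T and NK cells, B cells, erythroid cells, megakaryocytes, and stromal and endothelial cells had fewer than 5 members tested and are given as values.

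Genes were named by a rule set before the data were examined. For each inhibitor against DMSO the rule takes the 12 largest rises and the 12 largest falls with an adjusted p under 0.05, no overlap between the libraries and at least 5 FPKM in the higher group. For each list it takes up to 4 members with the smallest adjusted p, or the 2 most abundant where none passed, and between inhibitors the 5 largest differences each way. Nras, Map2k1, Map2k2, Mtor and Pik3cd were always named. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

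Relative depth was read from the smallest steps between low values, and no precision from counting could be computed. The procedure was tested on simulated data, drawn from a normal distribution around each gene's mean over all libraries with its moderated SD, with log2 changes of 0.5, 1 and 2 planted. For PD325901, RAD001 and GDC0941, 52.2%, 54.2% and 52.4% of changes of 0.5 were recovered, 95.2%, 90.4% and 95.0% of changes of 1, and 100% of changes of 2. False calls made up 2.37%, 5.68% and 2.34% of the calls. A shift of -0.5 planted in the mitosis list was called in all 3 comparisons, and of the 23 other lists 0, 0 and 1 were called. The genes were simulated as independent of each other, whereas the estimated inter-gene correlation was 0.922 for mitosis and 0.811 for sterol synthesis. These counts therefore cannot show how often lists of correlated genes are called falsely.

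Whether the replicate numbers pair the libraries was checked by correlating the deviations from the group mean. All 3 pairs were above 0.1 for PD325901 and RAD001 against DMSO and for RAD001 against PD325901 and GDC0941, but not for GDC0941 against DMSO (lowest r = 0.0354) or PD325901 (lowest r = -0.139). All 3 libraries correlated best with their own number for PD325901 against DMSO and GDC0941 against RAD001. Only 1 of 3 did for RAD001 or GDC0941 against DMSO and for PD325901 against RAD001, and 2 for PD325901 against GDC0941. Where replicate 1 alone deviates alike in each group, correlations above 0.1 can arise without pairing. Since the labels name no pairs, the replicate block was fitted as an alternative only. The other alternatives planned were a pseudocount of 0.1 or 5 FPKM, no filter or a filter at 5 FPKM, median-ratio scaling, quantile normalization, only the 2 groups compared, limma library weights, a minimum log2 change of 1, an estimated inter-gene correlation, and leaving out each library in turn. Leaving out the replicate 1 library of every group, leaving out Psap and Fth1, and the estimated correlation with the block were added after seeing the data. Correlations between comparisons that share the DMSO libraries were set beside 100 simulations of unchanged groups. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Reads were not used here.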

Results

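The data were RNA-seq profiles of 12 libraries from mouse primary acute myeloid leukaemia cells carrying NRASG12V and the MLL-AF9 fusion. The cells had been cultured for 24 h with the vehicle DMSO, 20 µM PD325901, 26 µM RAD001 or 20 µM GDC0941, with 3 libraries in each of the 4 groups. PD325901 inhibits the kinases MEK1 and MEK2, RAD001 (everolimus) inhibits the mTOR complex that contains raptor, and GDC0941 inhibits class I PI3 kinases. The 3 drugs are structurally unrelated and their doses were not matched for potency. The values were FPKM per gene symbol, and 10305 genes with a mean of at least 1 FPKM were tested. Read counts were not part of the values, so absolute depth was unknown. Relative depth, read from the smallest steps of the values, ran from 0.847 to 1.21 of that of DMSO replicate 1. Spearman correlations across genes were 0.966 to 0.996 within groups and 0.875 to 0.965 between groups. No label states that the replicates came from separate cultures or animals, so every p-value measures only the spread between these samples. Means are given ± SD with n = 3, and log2 changes ± SE from limma, with p adjusted by the Benjamini-Hochberg method for genes and for limma camera tests of gene lists. Log2 changes were taken after adding 1 FPKM, which understates the change of low genes. Genes given in brackets as the exceptions within a list were chosen after their values were seen.

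The comparison of PD325901 with DMSO asks which transcripts differed after 24 h with the MEK inhibitor. The direct output genes of the ERK pathway fell. Dusp6, the ERK phosphatase that is itself induced by ERK, fell from 87.7 ± 26.9 to 5.85 ± 0.737 FPKM (log2 change -3.66 ± 0.17, adjusted p = 2.4e-07), by limma. The ERK-driven transcription factor Etv5 fell from 18.1 ± 1.17 to 0.0807 ± 0.0431 FPKM (log2 change -4.14 ± 0.19, adjusted p = 2.4e-07). The growth regulator Myc fell from 22.5 ± 2.84 to 1.11 ± 0.131 FPKM (log2 change -3.47 ± 0.10, adjusted p = 7.41e-09). Cyclin D1, the product of Ccnd1 that links growth signals to the cell cycle, fell from 161 ± 26.2 to 3.21 ± 0.616 FPKM (log2 change -5.27 ± 0.43, adjusted p = 6.7e-06). The receptor Epha2, another ERK target, was 0.172 ± 0.113 against 2.86 ± 0.164 FPKM. Of the fixed list of ERK output and feedback genes, 17 of 23 fell, also 17 adjusted over the list alone, and the other 6 did not pass (median log2 change -1.72, adjusted p = 1.63e-07, adjusted p = 0.164 with an estimated correlation). The size of the change of a low gene depended on the value added before the logarithm. For Etv5, PD325901 against DMSO, it was -6.68 with 0.1 added and -2.18 with 5 added.

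Chemokine genes were among the largest falls with PD325901. The monocyte chemoattractants Ccl2, Ccl7 and Ccl12 fell, Ccl2 from 2025 ± 271 to 30.4 ± 15.8 FPKM (log2 change -6.13 ± 0.32, adjusted p = 5.13e-07) and Ccl7 from 974 ± 153 to 4.12 ± 3.09 FPKM (log2 change -7.72 ± 0.58, adjusted p = 4.23e-06), by limma. Ccl12 changed by -5.78 ± 0.52 on the log2 scale. The neutrophil chemoattractant Cxcl2 (-4.20 ± 0.64) and the macrophage chemokines Ccl4 (-4.16 ± 0.42) and Ccl9 (-2.24 ± 0.15) fell as well. The matrix proteases Mmp12, or macrophage elastase, and Mmp13, a collagenase, went to 4.41 ± 0.501 and 0.358 ± 0.124 FPKM, from 308 ± 100.2 and 27.8 ± 9.60 with DMSO. The plasminogen activator Plau (-4.25 ± 0.34), the surface glycoprotein Pdpn (-4.89 ± 0.51) and the matrix phosphoprotein Spp1 (-4.86 ± 0.69) fell too. Spp1 varied widely with DMSO, at 7245, 1437, 1679 FPKM in the 3 libraries. Of the list of NF-kB targets, cytokines and chemokines 11 of 25 fell and 2 rose, or 12 and 2 adjusted over the list alone (median log2 change -0.91, adjusted p = 0.0141, adjusted p = 0.560 with an estimated correlation).

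Among the largest rises with PD325901, Apoe, the apolipoprotein of macrophages, rose from 69.2 ± 26.8 to 558 ± 322 FPKM (log2 change 2.94 ± 0.63, adjusted p = 0.00300). Acp5, the tartrate-resistant acid phosphatase of osteoclasts and macrophages, rose from 15.2 ± 5.59 to 103 ± 36.1 FPKM (log2 change 2.67 ± 0.27, adjusted p = 2.2e-05). Fcgrt, the neonatal Fc receptor, rose from 5.19 ± 0.341 to 38.1 ± 10.0 FPKM (log2 change 2.63 ± 0.21, adjusted p = 5.14e-06). The fatty acid binding protein Fabp3 (2.28 ± 0.24), the lysosomal amidase Naaa (2.33 ± 0.39) and the phospholipase Ddhd1 (2.34 ± 0.25) rose. Id3, an inhibitor of DNA binding by basic helix-loop-helix factors, rose by 2.60 ± 0.40. The membrane proteins Tmem37 (2.85 ± 0.21) and Cd300lg (2.41 ± 0.14) rose. So did the cytoskeletal adaptor Sorbs3 (2.68 ± 0.30), the leucine-rich repeat gene Lrrc14b (2.51 ± 0.21) and the kallikrein Klk1b27 (2.35 ± 0.18), whose near-identical relatives make its assignment uncertain.

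Growth and biosynthesis genes fell together with PD325901. In the list of ribosome biogenesis genes, which build ribosomal RNA and its particles, 30 of 30 members fell, also 30 adjusted over the list alone (median log2 change -1.13, adjusted p = 1.84e-16, adjusted p = 0.172 with an estimated correlation). Among them were Nop58 (-2.17 ± 0.08), Mybbp1a (-1.26 ± 0.07), Nop2 (-1.26 ± 0.08) and Ncl (-1.19 ± 0.07). Of the S phase and DNA replication list 29 of 30 fell, also 29 adjusted over the list alone (median log2 change -1.36, adjusted p = 4.86e-08, adjusted p = 0.507 with an estimated correlation). They included the replication clamp Pcna (-1.35 ± 0.18), the primase Prim1 (-1.36 ± 0.19) and the loading factor Cdc6 (-1.34 ± 0.18). The exception, E2f2, rose by 0.56 ± 0.16 and was chosen after its values were seen. In mitosis 26 of 28 fell, or 27 adjusted over the list alone (median log2 change -1.16, adjusted p = 5.99e-06, adjusted p = 0.560 with an estimated correlation). The kinases Aurka (-1.39 ± 0.23) and Bub1 (-1.32 ± 0.24) and the F-box cyclin Ccnf (-1.19 ± 0.24) were among these. The serine synthesis enzymes Phgdh (-2.11 ± 0.14) and Psat1 (-2.93 ± 0.18), the mitochondrial Shmt2 (-1.48 ± 0.12) and the glutamine transporter Slc1a5 (-1.31 ± 0.09) fell in the ATF4 and amino acid list. In that list 20 of 29 fell and 1 (Cebpb) rose, the same counts adjusted over the list alone (median log2 change -0.80, adjusted p = 5.63e-06, adjusted p = 0.374 with an estimated correlation).

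Metabolic lists fell as well. Sterol synthesis had 18 of 23 members lower, also 18 adjusted over the list alone (median log2 change -0.82, adjusted p = 0.000153, adjusted p = 0.560 with an estimated correlation). Examples were Lss (-2.04 ± 0.28), Sqle (-1.57 ± 0.27) and Fdps (-1.55 ± 0.26). Fatty acid synthesis had 9 of 15 lower and 1 (Acsl1) higher, or 11 and 1 adjusted over the list alone (median log2 change -0.93, adjusted p = 0.0141, adjusted p = 0.569 with an estimated correlation). The falls included the desaturase Scd2 (-3.61 ± 0.50), the synthase Fasn (-1.81 ± 0.34) and their regulator Srebf1 (-0.97 ± 0.10). In glycolysis and hypoxia 21 of 25 fell, or 23 with 1 rise adjusted over the list alone (median log2 change -0.97, adjusted p = 1.14e-05, adjusted p = 0.541 with an estimated correlation). Pgk1 (-1.90 ± 0.17), Eno1 (-1.01 ± 0.10), Pkm2 (-0.81 ± 0.08) and Pfkp (-1.05 ± 0.11) are glycolytic enzymes in that list. Of the ER stress response list 14 of 17 fell, or 16 adjusted over the list alone (median log2 change -0.71, adjusted p = 7.29e-06, adjusted p = 0.446 with an estimated correlation), such as Creld2 (-1.37 ± 0.12), Hyou1 (-1.35 ± 0.13), Manf (-1.28 ± 0.12) and Pdia6 (-1.16 ± 0.11).

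Neutrophil maturation markers rose with PD325901, 14 of 23 higher and 1 (Il1r2) lower, or 15 and 2 adjusted over the list alone (median log2 change 1.00, adjusted p = 2.45e-05, adjusted p = 0.374 with an estimated correlation). The G-CSF receptor Csf3r rose from 32.3 ± 2.52 to 105 ± 6.47 FPKM (log2 change 1.67 ± 0.12, adjusted p = 3.79e-06). The calprotectin subunits S100a8 and S100a9 rose by 1.07 ± 0.17 and 1.11 ± 0.19, or by 0.68 and 0.67 after quantile normalization, and the leukolysin Mmp25 by 1.27 ± 0.15. The primary granule list did not pass as a set (adjusted p = 0.450 by limma camera with Benjamini-Hochberg adjustment), with a median of -0.13, a mean of 0.05 and an upward test. In it 5 of 13 rose, led by the myeloid regulators Cebpa (1.67 ± 0.18) and Cebpe (0.90 ± 0.15) and by Mgst1 (1.74 ± 0.36), and 3 fell, led by the protease Ctsg (-1.94 ± 0.31), or 5 and 4 adjusted over the list alone. Lysosome and TFEB targets rose as a set, with 12 of 30 higher and 3 lower, the same adjusted over the list alone (median log2 change 0.26, adjusted p = 0.00103, adjusted p = 0.507 with an estimated correlation). Their mean was -0.08, since it counts the 0 listed for Psap, 1 of the 3 lower, the list passed without Psap as well (adjusted p = 0.000122), and the named rises were Sgsh (0.93 ± 0.11) and Map1lc3b (0.52 ± 0.07). Psap, the precursor of the saposins, was listed at 0 in all 3 PD325901 libraries and at 3004, 3797, 3816 FPKM with DMSO. The values do not tell an absent transcript from a gene skipped when FPKM were made, so no fall of Psap is claimed.

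Lists without a call for PD325901 held single genes that changed. Among BCL2 family genes 4 of 16 rose and 7 fell, or 4 and 8 adjusted over the list alone (adjusted p = 0.545). The survival genes Bcl2l1 (-2.51 ± 0.11) and Bcl2 (-2.31 ± 0.19) were lower and the death-promoting Bmf (1.90 ± 0.18) and Bcl2l11 (1.09 ± 0.10) higher. Of the STAT5 and cytokine receptor list 9 of 19 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.272). Ccnd2 (-3.13 ± 0.19) and Id1 (-1.11 ± 0.16) were lower and Gadd45b (1.59 ± 0.21) higher. Its median was 0.26, its mean -0.09 and its test upward. Of the MLL fusion and HoxA list 7 of 16 fell, as Hmgb3 (-1.57 ± 0.16) and Cbx5 (-0.91 ± 0.14), and 2 rose, as the receptor Flt3 (0.95 ± 0.16), the same adjusted over the list alone (adjusted p = 0.102). In the stem and progenitor list 6 of 11 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.512). Cd34 (-2.39 ± 0.40) and Lmo2 (-0.78 ± 0.15) were lower and Kit (0.91 ± 0.16) higher. Monocyte and macrophage markers split, 10 of 29 higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.148). The scavenger receptor Msr1 (-2.23 ± 0.15), the endotoxin co-receptor Cd14 (-2.22 ± 0.27) and the mannose receptor Mrc1 (-1.39 ± 0.18) fell.

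Antigen presentation genes were 7 of 24 higher and 3 lower, or 5 and 2 adjusted over the list alone, and did not pass (adjusted p = 0.0996 by limma camera, Benjamini-Hochberg; 0.00333 without PD325901 replicate 1, 0.0150 without replicate 1 of every group and 0.0351 with library weights). Cd80 (-0.87 ± 0.10) fell and Batf3 (1.03 ± 0.25) rose. Of 26 interferon response genes only Ifitm3 (-0.80 ± 0.13) passed, also 1 adjusted over the list alone (adjusted p of the list = 0.506). The list median was -0.20, 0.18 and 0.23 in the replicate 1, 2 and 3 pairs, and without the replicate 1 library of every group the list passed, higher (0.0237). FOXO targets rose in 6 and fell in 3 of 24, or 6 and 2 adjusted over the list alone (adjusted p = 0.269). Tsc22d3 (1.10 ± 0.20) and Ccng2 (0.66 ± 0.12) were higher. Of 17 p53 targets 7 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.437), with Mdm2 (-0.80 ± 0.09), Aen (-0.60 ± 0.09) and Rps27l (-0.72 ± 0.14) lower. The Ras pathway and drug target list had 8 of 30 members higher and 8 lower, or 8 and 10 adjusted over the list alone (adjusted p = 0.682), with a median of -0.08, a mean of 0.01 and an upward test. Mapk3 (0.82 ± 0.10) rose and Eif4ebp1 (-0.62 ± 0.10) and Fkbp1a (-0.52 ± 0.10) fell.

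Among the drug target genes, the PD325901 targets Map2k1 (-0.31 ± 0.11) and Map2k2 (-0.31 ± 0.10) fell, and the PI3 kinase subunit gene Pik3cd (0.30 ± 0.11) rose, by limma with adjusted p = 0.0365, 0.0308 and 0.0424. With 1 library fewer these calls often ended, at smaller or larger changes. The Map2k1 call ended without DMSO replicate 1 or any 1 of the PD325901 libraries (adjusted p = 0.0532 to 0.141, log2 changes -0.34 to -0.20). The Map2k2 call ended without any 1 of the DMSO libraries or PD325901 replicate 2 or 3 (0.0520 to 0.101, log2 changes -0.34 to -0.27), and the Pik3cd call ended without the same libraries as for Map2k2 (0.0517 to 0.148, log2 changes 0.23 to 0.35). The Pik3cd call also ended with no filter (0.0557) and with only the 2 groups compared (0.0629). Nras (-0.19 ± 0.07) and Mtor (-0.08 ± 0.14) did not pass, with Nras at adjusted p = 0.0591, or 0.0427 without PD325901 replicate 1, 0.00998 without the replicate 1 library of every group, 0.0479 with no filter and 0.000535 with library weights.

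Across all genes, 4802 of 10305 genes (46.6%) changed with PD325901 by limma, 1893 higher and 2909 lower, and 905 of them by at least 1 on the log2 scale, 296 higher and 609 lower. After quantile normalization more rose than fell, 2675 against 2455. All PD325901 libraries lay above all DMSO libraries for 2661 genes and below them for 3805, where chance gives 10% for 3 against 3 in both directions together. Of the 24 lists tested 12 passed, 2 higher and 10 lower, and 0 with an estimated correlation by limma camera, where 2 had an unadjusted p under 0.05.

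**Figure D1:**
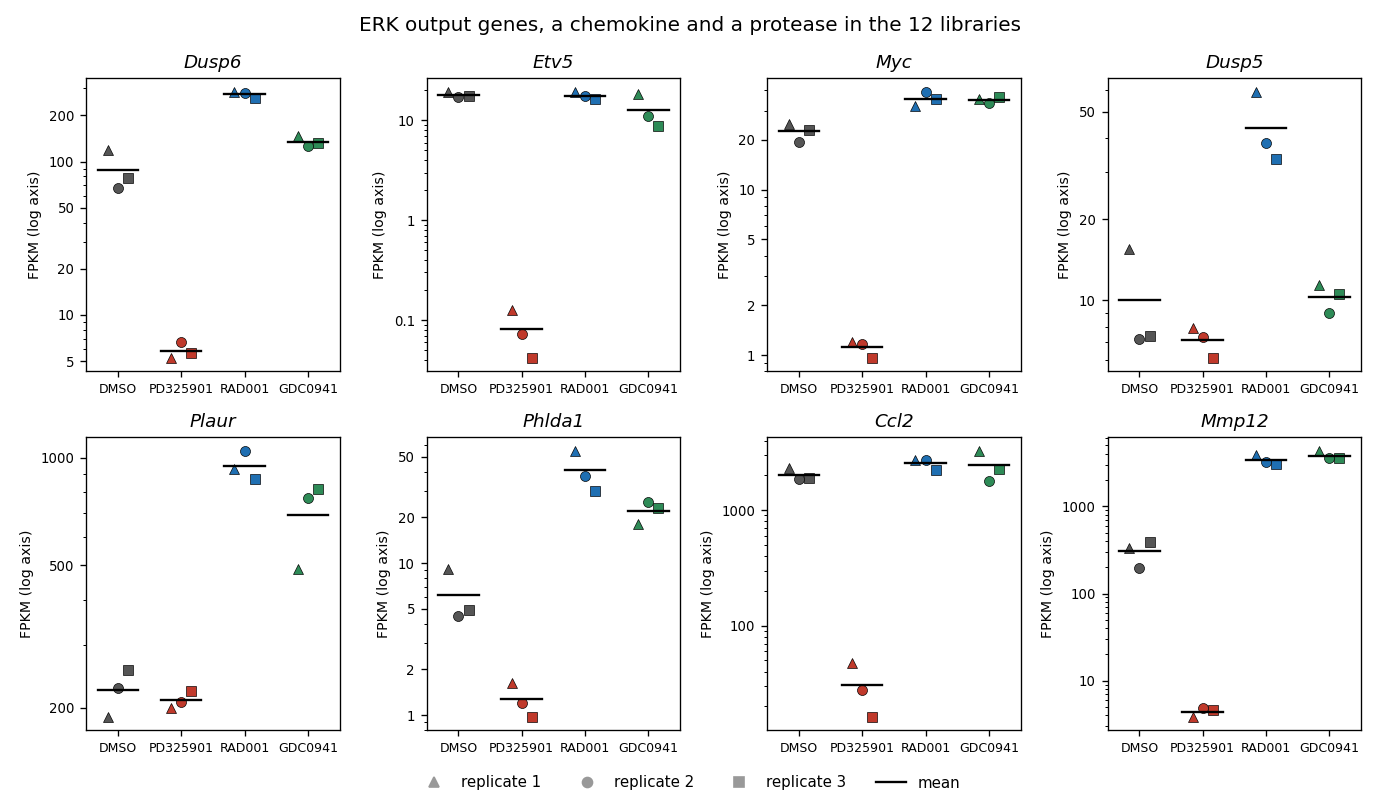
FPKM of 8 genes in the 12 libraries by group, on a log axis (points are libraries, black lines are group means). Dusp6, Etv5, Myc and Ccl2 lie lowest with PD325901, and Dusp5, Plaur, Phlda1 and Mmp12 lie higher with RAD001 than with DMSO.

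The comparison of RAD001 with DMSO asks which transcripts differed after 24 h with the mTOR inhibitor. Chemokine genes were among the largest rises. The neutrophil chemoattractant Cxcl3 rose from 9.39 ± 8.91 to 1017 ± 269 FPKM (log2 change 6.90 ± 0.47, adjusted p = 6.61e-06), by limma. Serpinb2, the plasminogen activator inhibitor of macrophages, rose from 18.9 ± 11.3 to 1551 ± 105 FPKM (log2 change 6.42 ± 0.32, adjusted p = 7.87e-07). Ppbp, the precursor of a platelet chemokine, rose from 4.49 ± 2.25 to 183 ± 16.8 FPKM (log2 change 5.14 ± 0.22, adjusted p = 2.9e-07). The related chemokines Cxcl2 (2.97 ± 0.64) and Cxcl5 (3.03 ± 0.16) rose, and so did the proteases Mmp13 (4.59 ± 0.26) and Mmp12 (3.50 ± 0.21). Fn1, or fibronectin, rose by 3.31 ± 0.39 and Clec7a, the beta-glucan receptor dectin 1, by 3.22 ± 0.36. Tm7sf4, needed for macrophage fusion, rose by 2.85 ± 0.26, the lysozyme-like Lyzl4 by 3.48 ± 0.18 and the glycosyltransferase Galnt9 by 2.96 ± 0.13. Of the NF-kB, cytokine and chemokine list 9 of 25 rose and 1 (Cxcl10) fell, or 11 and 1 adjusted over the list alone (median log2 change 0.56, adjusted p = 0.00293, adjusted p = 0.560 with an estimated correlation). Ccl6 (1.76 ± 0.18), Ccl9 (1.64 ± 0.15) and the inhibitor of apoptosis Birc3 (0.81 ± 0.12) rose. That list did not pass without RAD001 replicate 1 (adjusted p = 0.0708).

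The ERK output list rose with RAD001, 14 of 23 members higher and 1 (Ccnd1) lower, the same adjusted over the list alone (median log2 change 0.57, adjusted p = 8.11e-05, adjusted p = 0.320 with an estimated correlation). Dusp6 rose from 87.7 ± 26.9 to 275 ± 14.1 FPKM (log2 change 1.68 ± 0.17, adjusted p = 7.74e-05) and the second ERK phosphatase gene Dusp5 rose from 10.0 ± 4.74 to 43.6 ± 13.8 FPKM (log2 change 2.05 ± 0.27, adjusted p = 0.000296), by limma. The urokinase receptor Plaur (2.09 ± 0.18) and Phlda1 (2.55 ± 0.26) rose as well. The STAT5 and cytokine receptor list rose too, 9 of 19 higher and 2 lower, or 11 and 3 adjusted over the list alone (median log2 change 0.40, adjusted p = 0.00359, adjusted p = 0.168 with an estimated correlation). In it Csf2ra (0.86 ± 0.10) and Csf2rb (2.14 ± 0.14), which encode chains of the receptor for GM-CSF, rose. The related Csf2rb2 (2.27 ± 0.22) and Cish (1.76 ± 0.24), a STAT5 feedback gene, rose as well. Of the Ras pathway and drug target list 11 of 30 rose and 2 fell, or 13 and 2 adjusted over the list alone (median log2 change 0.20, adjusted p = 0.00677, adjusted p = 0.374 with an estimated correlation). In it Rictor (0.53 ± 0.11) rose and Mllt3 (-0.57 ± 0.11) fell.

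Proliferation genes fell with RAD001. In mitosis 28 of 28 members fell, also 28 adjusted over the list alone (median log2 change -1.83, adjusted p = 3.51e-16, adjusted p = 0.374 with an estimated correlation). Among them were Aurka (-1.90 ± 0.23), Bub1b (-1.80 ± 0.21), Kif11 (-1.81 ± 0.23) and Bub1 (-1.86 ± 0.24). In S phase and DNA replication 29 of 30 fell and 1 rose, the same adjusted over the list alone (median log2 change -1.57, adjusted p = 6.65e-15, adjusted p = 0.374 with an estimated correlation). Replication genes that fell were Cdc45 (-1.74 ± 0.22), Prim1 (-1.59 ± 0.19) and Cdc6 (-1.57 ± 0.18). In the 3 pairs of libraries with the same replicate number the mitosis median was -1.30 in replicate 1, -2.04 in replicate 2 and -2.16 in replicate 3. Of 30 ribosome biogenesis genes 9 fell, also 9 adjusted over the list alone (median log2 change -0.09, adjusted p = 0.0454, adjusted p = 0.670 with an estimated correlation), with medians of 0.10, -0.13 and -0.20 in the 3 pairs. The nucleolar Ncl (-0.57 ± 0.07) and the spermidine synthase Srm (-0.79 ± 0.15) fell. That list did not pass without DMSO replicate 2 or 3 (0.107 and 0.0873), without RAD001 replicate 2 or 3 (0.0773 and 0.224) or after median-ratio scaling (0.0657). It did not pass with the replicate block in the model (0.0713) or with only the 2 groups compared (0.0642), by limma camera. The deviations of all 3 RAD001 and DMSO pairs correlated above 0.1, but only 1 of the 3 RAD001 libraries correlated best with its own number.

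Biosynthetic lists fell with RAD001. The ATF4 and amino acid list had 24 of 29 members lower and 2 (Slc7a11 and Cebpb) higher, or 26 and 2 adjusted over the list alone (median log2 change -0.93, adjusted p = 8.23e-13, adjusted p = 0.141 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, fell from 37.2 ± 2.49 to 5.38 ± 0.839 FPKM (log2 change -2.59 ± 0.14, adjusted p = 9.22e-07). Shmt2 (-1.93 ± 0.12), Asns (-1.79 ± 0.14) and Pck2 (-1.83 ± 0.13) fell, by limma. Sterol synthesis had 17 of 23 lower, or 19 adjusted over the list alone (median log2 change -0.96, adjusted p = 3.23e-07, adjusted p = 0.507 with an estimated correlation), with medians of -0.32, -1.12 and -1.25 in the replicate 1, 2 and 3 pairs. The enzymes Fdps (-1.61 ± 0.26), Dhcr7 (-1.53 ± 0.24), Pmvk (-0.96 ± 0.15) and Mvd (-0.90 ± 0.16) fell. Fatty acid synthesis had 7 of 15 lower and 1 (Me1) higher, or 9 and 1 adjusted over the list alone (median log2 change -0.43, adjusted p = 0.00483, adjusted p = 0.560 with an estimated correlation), with the desaturase Scd2 (-2.49 ± 0.50). Glycolysis and hypoxia genes fell in 11 of 25, and 1, the glucose transporter gene Slc2a1, rose, the same adjusted over the list alone (median log2 change -0.38, adjusted p = 0.000572, adjusted p = 0.560 with an estimated correlation). Among these fell Ldha (-1.11 ± 0.20), Tpi1 (-1.13 ± 0.25), Pfkp (-0.96 ± 0.11) and the mitophagy receptor Bnip3 (-1.58 ± 0.25).

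Genes of early granulocytes fell with RAD001 while late ones rose. The neutrophil elastase gene Elane fell from 34.6 ± 8.60 to 1.16 ± 1.55 FPKM (log2 change -4.24 ± 0.37, adjusted p = 3.27e-05), and the related serine proteases Prtn3 and Ctsg fell from 65.3 ± 6.04 to 4.25 ± 3.64 FPKM (log2 change -3.86 ± 0.34, adjusted p = 3.14e-05) and from 71.4 ± 5.58 to 7.21 ± 5.17 FPKM (log2 change -3.31 ± 0.31, adjusted p = 4.16e-05), by limma. Mpo, myeloperoxidase, fell by a log2 change of -3.07 ± 0.32. In the primary granule list 9 of 13 fell and the other 4 did not pass, also 9 adjusted over the list alone (median log2 change -1.78, adjusted p = 5.12e-06, adjusted p = 0.141 with an estimated correlation). Ms4a3 (-2.70 ± 0.21) and the ficolin Fcnb (-2.19 ± 0.20) fell. Neutrophil maturation markers rose in 12 of 23 and fell in 1 (Chi3l3), or 13 and 1 adjusted over the list alone (median log2 change 0.41, adjusted p = 0.00120, adjusted p = 0.488 with an estimated correlation). The collagenase Mmp8 rose from 266 ± 62.1 to 1798 ± 237 FPKM (log2 change 2.77 ± 0.22, adjusted p = 1.97e-05). Mmp9 (2.08 ± 0.41), Mmp25 (0.99 ± 0.15) and the chemokine receptor Cxcr2 (0.99 ± 0.20) rose. Among monocyte and macrophage markers 7 of 29 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.258). Cd14 (2.07 ± 0.27), Itgam (1.27 ± 0.08) and Csf1r (0.85 ± 0.12) were higher and Mrc1 (-2.38 ± 0.18) lower. That list passed without RAD001 replicate 1 (adjusted p = 0.0430) or without the replicate 1 library of every group (0.0177).

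Other falls with RAD001 included the fatty acid binding proteins Fabp4 (-4.47 ± 0.69) and Fabp5 (-3.01 ± 0.29), the chemokine Ccl12 (-4.27 ± 0.52), the mast cell protease Cpa3 (-3.55 ± 0.69), the stress cytokine Gdf15 (-2.95 ± 0.23), the carbonyl reductase Cbr2 (-2.93 ± 0.28) and the kallikrein Klk1b11 (-3.71 ± 0.44), whose near-identical relatives make its assignment uncertain. Cpa3 with DMSO was 139, 16.9, 14.9 FPKM in the 3 libraries. The MLL fusion and HoxA list did not pass (adjusted p = 0.113 by limma camera, Benjamini-Hochberg; 0.0450 without RAD001 replicate 1), with 5 of 16 lower and 2 higher, the same adjusted over the list alone. The proto-oncogene Myb (-1.63 ± 0.12), Hmgb3 (-1.29 ± 0.16) and Cbx5 (-0.82 ± 0.14) fell. Of the stem and progenitor list 4 of 11 fell and 1 rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.0591; 0.0430 without RAD001 replicate 1, 0.0406 without DMSO replicate 3, 0.0473 with a pseudocount of 5 and 0.0304 with only the 2 groups compared). Lmo2 (-0.75 ± 0.15) and Cd34 (-1.70 ± 0.40) were lower and Gata2 (2.23 ± 0.52) higher. Fth1, the heavy chain of the iron store ferritin, was listed at 0 in all 3 RAD001 libraries and at 20209.7, 15265, 15048 FPKM with DMSO. As for Psap, an absent transcript is not told from a skipped gene, and no fall of Fth1 is claimed.

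The remaining lists did not pass with RAD001. In the interferon response 3 of 26 fell and 1 rose, or 1 and 1 adjusted over the list alone (adjusted p = 0.236 by limma camera), and Ifit2 (-1.64 ± 0.41) fell, though not with only the 2 groups compared (adjusted p = 0.0519). The list median was -1.04 in the replicate 1 pair, 0.30 in the replicate 2 pair and 0.27 in the replicate 3 pair. The list passed, lower, without RAD001 replicate 2 (adjusted p = 0.0208) or without RAD001 replicate 3 (0.0128). FOXO targets rose in 5 and fell in 4 of 24, the same adjusted over the list alone (adjusted p = 0.194; 0.0412 with no filter). Trib1 (1.32 ± 0.21) was higher and Sesn1 (-1.32 ± 0.20) and Pik3ip1 (-1.17 ± 0.19) lower. Antigen presentation had 3 of 24 higher and 2 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.506). The costimulators Cd86 (1.10 ± 0.22) and Cd80 (0.52 ± 0.10) were higher. Lysosome and TFEB targets had 6 of 30 higher and 2 lower, or 5 and 2 adjusted over the list alone (median -0.03, mean -0.01, test upward, adjusted p = 0.826). Cln3 (0.56 ± 0.12) and Gabarapl1 (0.61 ± 0.14) were higher and Sgsh (-0.55 ± 0.11) lower. Of 17 p53 targets 2 rose, Cdkn1a (0.78 ± 0.15) and Mdm2 (0.50 ± 0.09), and only Gdf15 fell, the same adjusted over the list alone (adjusted p = 0.945).

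BCL2 family genes rose in 2 and fell in 2 of 16, the same adjusted over the list alone (adjusted p = 0.477 by limma camera, Benjamini-Hochberg), with Bcl2l11 (0.50 ± 0.10) higher and Bid (-1.13 ± 0.14) lower. Of 17 ER stress genes 2 fell, or 1 adjusted over the list alone (adjusted p = 0.682), with Sdf2l1 (-0.44 ± 0.11). Nras (0.28 ± 0.07) rose (adjusted p = 0.0159), a call that ended without DMSO replicate 1 or 2 or RAD001 replicate 2 (0.0543, 0.0539 and 0.0508). Pik3cd (0.34 ± 0.11) rose (adjusted p = 0.0383), a call that ended without any 1 of the 6 libraries (0.0563 to 0.122), with no filter (0.0521) and after median-ratio scaling (0.0504) or quantile normalization (0.111). The drug target gene Mtor (0.13 ± 0.14) and the genes Map2k1 (0.13 ± 0.11) and Map2k2 (-0.10 ± 0.10) did not pass. With library weights Mtor (0.0415) and Map2k1 (0.00534) passed, as did Map2k1 without the replicate 1 library of every group (0.0287).

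Across all genes, 3224 of 10305 genes (31.3%) changed with RAD001 by limma, 1586 higher and 1638 lower, and 649 by at least 1 on the log2 scale, 269 higher and 380 lower. With library weights 6923 changed, 3596 higher and 3327 lower. More rose than fell with a filter at 5 FPKM too (1377 and 1102) and with median-ratio scaling (1682 and 1671). The libraries did not overlap for 2606 genes that were higher and 2633 that were lower, where chance gives 10% in both directions together. Of the 24 lists 13 passed, 5 higher and 8 lower, and 0 with an estimated correlation by limma camera, where 4 had an unadjusted p under 0.05.

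**Figure D2:**
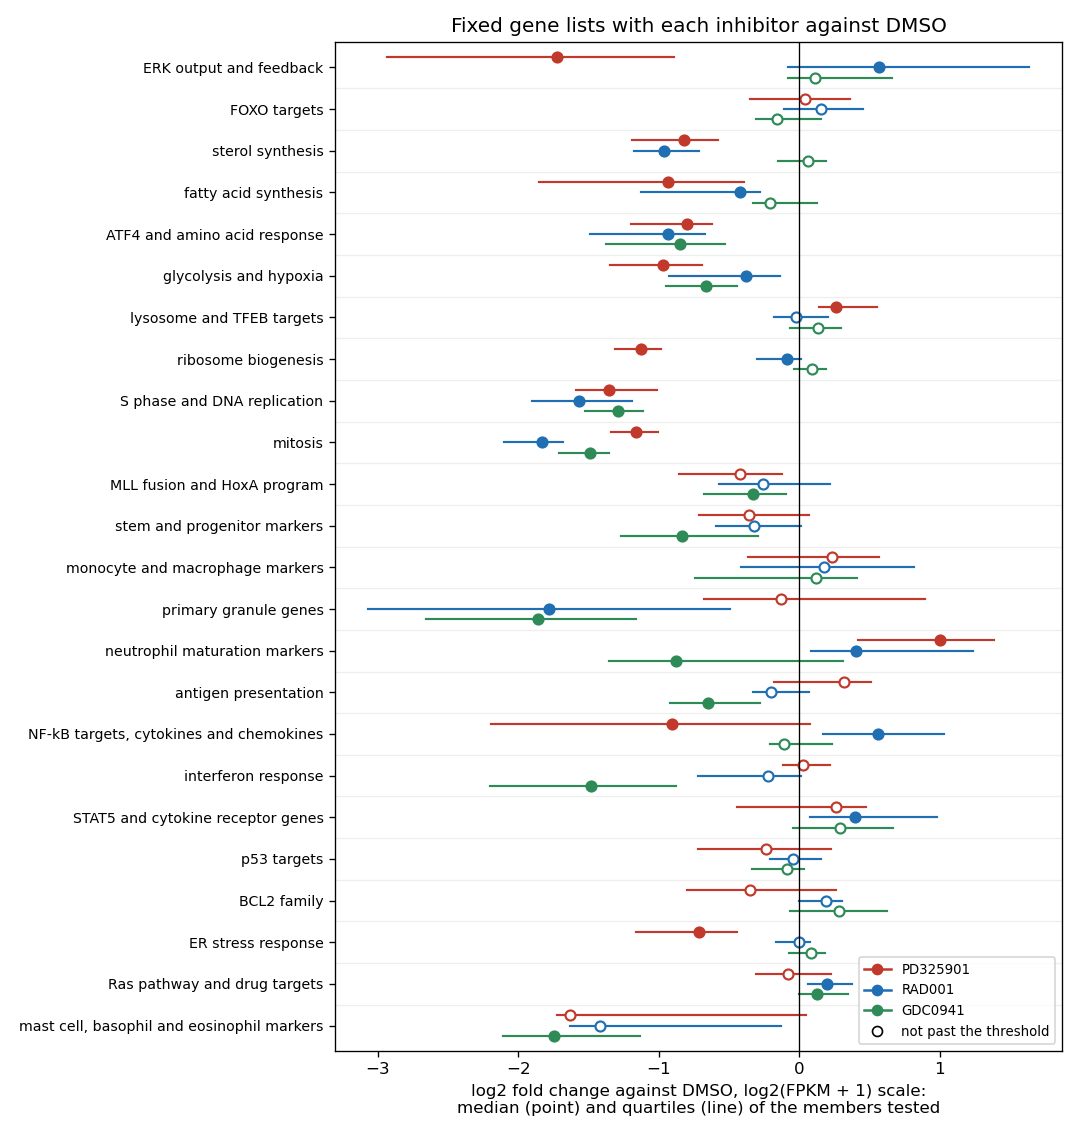
Median log2 change (point) and quartiles (line) of the members of each tested gene list with each inhibitor against DMSO; open points did not pass the list test. ERK output genes lie at -1.72 with PD325901 and 0.57 with RAD001, and interferon response genes at -1.48 with GDC0941.

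The comparison of GDC0941 with DMSO asks which transcripts depend on class I PI3 kinases. Interferon response genes were lower with GDC0941. The ubiquitin-like modifier Isg15 fell from 134 ± 45.9 to 19.2 ± 3.54 FPKM (log2 change -2.70 ± 0.35, adjusted p = 0.000484), by limma. The chaperone gene Rtp4 fell from 58.7 ± 5.12 to 12.4 ± 0.526 FPKM (log2 change -2.15 ± 0.27, adjusted p = 0.000393) and the antiviral Ifit1 from 16.4 ± 7.82 to 2.10 ± 0.425 FPKM (log2 change -2.41 ± 0.31, adjusted p = 0.000466). Ifit3 (-3.01 ± 0.43), Ifitm1 (-3.10 ± 0.31), the RNA sensor regulator Dhx58 (-1.47 ± 0.20) and the interferon-induced chemokine Cxcl10 (-2.92 ± 0.28) fell. Of the interferon response list 23 of 26 fell and the other 3 did not pass, or 25 fell adjusted over the list alone (median log2 change -1.48, adjusted p = 3.56e-13, adjusted p = 0.374 with an estimated correlation). Antigen presentation genes fell in 14 of 24 and rose in 1 (Itgax), or 15 and 1 adjusted over the list alone (median log2 change -0.65, adjusted p = 2.68e-05, adjusted p = 0.320 with an estimated correlation). The invariant chain Cd74 (-1.28 ± 0.22), the costimulator Cd40 (-1.39 ± 0.19), the peptide loader Tapbp (-0.63 ± 0.12) and the dendritic cell factor Zbtb46 (-0.58 ± 0.10) fell.

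Genes of granulocyte precursors fell with GDC0941. The granule proteases Ctsg and Prtn3 fell from 71.4 ± 5.58 to 6.94 ± 1.17 FPKM (log2 change -3.20 ± 0.31, adjusted p = 7.38e-05) and from 65.3 ± 6.04 to 6.32 ± 1.35 FPKM (log2 change -3.19 ± 0.34, adjusted p = 0.000137), by limma. Elane (-3.26 ± 0.37) fell as well. In the primary granule list 10 of 13 fell and 1 (Cebpa) rose, or 11 and 1 adjusted over the list alone (median log2 change -1.86, adjusted p = 7.29e-08, adjusted p = 0.141 with an estimated correlation). The granulocyte regulator Cebpe (-1.86 ± 0.15), Ms4a3 (-2.66 ± 0.21) and Fcnb (-1.90 ± 0.20) fell. Of the neutrophil maturation markers 13 of 23 fell and 4 rose, or 14 and 6 adjusted over the list alone (median log2 change -0.88, adjusted p = 0.0137, adjusted p = 0.560 with an estimated correlation). That call ended without GDC0941 replicate 1 (adjusted p = 0.200). The iron-binding lipocalin Lcn2 (-1.83 ± 0.20), Mmp25 (-1.29 ± 0.15) and the arginine deiminase Padi4 (-1.11 ± 0.13) fell and Arg2 (1.51 ± 0.22) rose. In the stem and progenitor list 7 of 11 fell, or 8 adjusted over the list alone (median log2 change -0.84, adjusted p = 5.09e-05, adjusted p = 0.141 with an estimated correlation). Ly6a, the stem cell antigen Sca-1, fell from 494 ± 37.7 to 27.4 ± 5.50 FPKM (log2 change -4.14 ± 0.50, adjusted p = 0.000337), and Myb (-1.67 ± 0.12), Gpr56 (-0.87 ± 0.12) and Erg (-0.75 ± 0.12) fell. Ly6a and Ly6c1 (-3.39 ± 0.48) have near-identical relatives and their assignment is uncertain. In the MLL fusion and HoxA list 6 of 16 fell, as Lmo2 (-0.88 ± 0.15), Flt3 (-0.84 ± 0.16) and Cbx5 (-0.71 ± 0.14), and 2 rose, the same adjusted over the list alone (median log2 change -0.33, adjusted p = 0.0105, adjusted p = 0.472 with an estimated correlation). With a filter at a mean of 5 FPKM that list did not pass (0.145). Lmo2 and Flt3 are also in the stem and progenitor list and Flt3 in antigen presentation, so the calls of these lists are not independent.

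Among the largest rises with GDC0941, the carbonic anhydrase Car4 rose from 1.29 ± 1.09 to 37.9 ± 10.9 FPKM (log2 change 4.15 ± 0.30, adjusted p = 1.58e-05), by limma. Clec7a rose from 27.6 ± 8.32 to 402 ± 168 FPKM (log2 change 3.76 ± 0.36, adjusted p = 7.31e-05), Mmp12 from 308 ± 100.2 to 3808 ± 468 FPKM (log2 change 3.67 ± 0.21, adjusted p = 8.86e-06) and the chemokine Ccl6 from 1002 ± 264 to 5850.4 ± 769.9 FPKM (log2 change 2.57 ± 0.18, adjusted p = 1.55e-05). Fn1 (3.72 ± 0.39), Tm7sf4 (2.51 ± 0.26), the adhesion receptor Selp (2.84 ± 0.20), the C-type lectin Cd209a (2.40 ± 0.44) and the inhibitory Fc receptor Fcgr2b (2.09 ± 0.19) rose. So did the cystine transporter Slc7a11 (2.00 ± 0.37), the cell cycle inhibitor Cdkn2b (2.28 ± 0.35) and the ERK-induced factor Egr2 (2.59 ± 0.33). Of the ERK output list 8 of 23 rose and 1 fell, or 8 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.0755 by limma camera, Benjamini-Hochberg). Plaur (1.60 ± 0.18) and Etv1 (0.99 ± 0.13) rose and Epha2 (-1.16 ± 0.11) fell. The list passed, higher, without DMSO replicate 1 (0.00986) or GDC0941 replicate 2 (0.0428), with no filter (0.0377) and with a filter at a mean of 5 FPKM (0.0491). Of 29 monocyte and macrophage markers 7 rose and 7 fell, or 9 and 9 adjusted over the list alone (adjusted p = 0.945), with a median of 0.12, a mean of -0.27 and an upward test. Cd14 (1.92 ± 0.27), Itgam (0.67 ± 0.08) and Sirpa (0.49 ± 0.07) rose and Cd300e (-1.02 ± 0.10) fell.

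Other large falls with GDC0941 were the platelet chemokine Pf4 (-4.23 ± 0.37), the macrophage actin-binding protein Aif1 (-3.10 ± 0.19), Ccl12 (-3.36 ± 0.52) and Cpa3 (-3.10 ± 0.69). Of the mast cell, basophil and eosinophil list 3 of 5 fell, also 3 adjusted over the list alone (median log2 change -1.75, adjusted p = 0.0173, adjusted p = 0.408 with an estimated correlation). That call ended without GDC0941 replicate 1 (adjusted p = 0.0646). Of the 3 genes, Mcpt8 (-1.13 ± 0.34) and Prg2 (-2.11 ± 0.67) passed narrowly (adjusted p = 0.0313 and 0.0416 by limma). Neither passed without any 1 of the GDC0941 libraries, without DMSO replicate 1 (0.111 and 0.142), with no filter (0.0572 and 0.0742) or after quantile normalization (0.0523 and 0.0503). Mcpt8 also lost the call with a pseudocount of 0.1 (0.0685) or without DMSO replicate 2 (0.0736), and Prg2 with a pseudocount of 5 (0.0594) or without DMSO replicate 3 (0.0509). Of the NF-kB, cytokine and chemokine list 2 of 25 rose, Ccl6 and Ccl9 (1.10 ± 0.15), and 2 fell, the same adjusted over the list alone (adjusted p = 0.844 by limma camera).

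Proliferation and amino acid genes fell with GDC0941. In mitosis 28 of 28 fell, also 28 adjusted over the list alone (median log2 change -1.49, adjusted p = 9.36e-16, adjusted p = 0.374 with an estimated correlation). Aurka (-1.74 ± 0.23), Mki67 (-1.57 ± 0.23), Kif11 (-1.44 ± 0.23) and Hmmr (-1.35 ± 0.22) fell. In S phase and DNA replication 27 of 30 fell and 1 rose, or 28 and 1 adjusted over the list alone (median log2 change -1.29, adjusted p = 7.87e-15, adjusted p = 0.374 with an estimated correlation). Mcm7 (-1.55 ± 0.25), Prim1 (-1.50 ± 0.19), E2f2 (-1.32 ± 0.16) and Cdc6 (-1.28 ± 0.18) fell. The mitosis median was -0.73 in the replicate 1 pair of libraries, -1.82 in the replicate 2 pair and -1.92 in the replicate 3 pair, and that of S phase -0.61, -1.67 and -1.61. In the ATF4 and amino acid list 22 of 29 fell and 3 rose, or 24 and 3 adjusted over the list alone (median log2 change -0.85, adjusted p = 7.61e-13, adjusted p = 0.141 with an estimated correlation). Phgdh (-2.41 ± 0.14), Pck2 (-1.60 ± 0.13), Sesn2 (-1.37 ± 0.09) and Shmt2 (-1.37 ± 0.12) fell. Glycolysis and hypoxia genes fell in 15 of 25, or 17 adjusted over the list alone (median log2 change -0.67, adjusted p = 2.25e-07, adjusted p = 0.472 with an estimated correlation). Pfkp (-0.72 ± 0.11), Gapdh (-0.60 ± 0.12), Gpi1 (-0.58 ± 0.10) and Pkm2 (-0.53 ± 0.08) fell.

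Sterol synthesis passed in 0 of 23 genes by limma with GDC0941, 3 at an unadjusted p under 0.05, and fatty acid synthesis in 0 of 15, 2 at an unadjusted p under 0.05, the same 0 adjusted over the list alone. Their lists did not pass (adjusted p = 0.819 and 0.666 by limma camera), with Fdps (-0.12 ± 0.26), Sc4mol (0.35 ± 0.17), Scd2 (-0.51 ± 0.50) and Acly (-0.11 ± 0.17). Acly passed without GDC0941 replicate 1 (-0.36, adjusted p = 0.0125). Without the replicate 1 library of every group Scd2 (-1.11, adjusted p = 6.82e-05), Fdps (-0.52, 0.00259) and Acly (-0.38, 0.00577) were lower, by limma, as were Scd2 (0.0396) and Fdps (0.0441) with library weights. The sterol median was 0.82 in the replicate 1 pair and -0.36 and -0.38 in the replicate 2 and 3 pairs, and the fatty acid median 0.66, -0.29 and -0.51 in the same order. Without the replicate 1 library of every group both lists passed, lower (adjusted p = 0.000989 and 0.0237). Of 17 ER stress genes 0 passed, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.506), with Hspa5 (-0.11 ± 0.21) and Calr (-0.03 ± 0.13). Of 30 ribosome biogenesis genes 3 rose, Utp20, Nop16 and Pes1, while 0 passed adjusted over the list alone by limma, where 8 had an unadjusted p under 0.05 (adjusted p of the list = 0.313). None of them passed without DMSO replicate 1 (adjusted p = 0.0719, 0.119 and 0.138), DMSO replicate 2 or GDC0941 replicate 2, or with only the 2 groups compared (0.0706, 0.0914 and 0.128).

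FOXO targets rose in 4 and fell in 2 of 24 with GDC0941, the same adjusted over the list alone (adjusted p = 0.879 by limma camera, Benjamini-Hochberg), with Trib1 (1.44 ± 0.21) and the insulin receptor substrate Irs2 (1.01 ± 0.14) higher and Sesn3 (-1.37 ± 0.17) lower. The STAT5 and cytokine receptor list had 6 of 19 higher and 2 lower, or 8 and 2 adjusted over the list alone (adjusted p = 0.0854; 0.0336 without GDC0941 replicate 1 and 0.0239 with no filter). Cish (1.55 ± 0.24) and Id1 (0.90 ± 0.16) were higher and Ccnd2 (-1.37 ± 0.19) and Ccnd3 (-0.64 ± 0.10) lower. BCL2 family genes rose in 8 and fell in 3 of 16, the same adjusted over the list alone (adjusted p = 0.196). Bid (-1.31 ± 0.14) and Pmaip1 (-1.12 ± 0.15) were lower and Bcl2a1b and Bcl2a1d, near-identical copies of uncertain assignment, higher by 1.60 ± 0.26 and 1.07 ± 0.15. Of 17 p53 targets 3 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.312), with Gdf15 (-1.11 ± 0.23). Of 30 lysosome and TFEB targets 6 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0996; 0.0304 with no filter and 0.0497 with only the 2 groups compared), with Gabarapl1 (0.88 ± 0.14) and the proton pump subunit Atp6ap1 (0.45 ± 0.09).

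The Ras pathway and drug target list rose with GDC0941, 8 of 30 higher and 1 lower, the same adjusted over the list alone (median log2 change 0.13, adjusted p = 0.0254, adjusted p = 0.464 with an estimated correlation). The median was 0.14, 0.19 and -0.02 in the replicate 1, 2 and 3 pairs. The call ended without GDC0941 replicate 1 or 2 (adjusted p = 0.0705 and 0.0796), without the replicate 1 library of every group (0.0501) and with a filter at a mean of 5 FPKM (0.0505). In it Nras (0.44 ± 0.07), Fkbp1a (0.75 ± 0.10) and Akt1 (0.29 ± 0.07) rose, while the drug target gene Pik3cd (0.25 ± 0.11) and Mtor (-0.02 ± 0.14), Map2k1 (0.06 ± 0.11) and Map2k2 (-0.10 ± 0.10) did not pass. Akt1 did not pass with only the 2 groups compared (adjusted p = 0.0535), and Pik3cd passed with library weights (0.0369) and without the replicate 1 library of every group (0.0184).

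Across all genes, 2503 of 10305 genes (24.3%) changed with GDC0941 by limma, 1194 higher and 1309 lower, and 589 by at least 1 on the log2 scale, 141 higher and 448 lower. Without DMSO replicate 2 the count was 1632, and without the replicate 1 library of every group it was 4281. With library weights it was 3849. More rose than fell after quantile normalization (1528 and 1293) and with a filter at 5 FPKM (997 and 814). The libraries did not overlap for 2097 genes that were higher and 1886 that were lower, where chance gives 10% in both directions together. Of the 24 lists 12 passed, 1 higher and 11 lower, and 0 with an estimated correlation by limma camera, where 4 had an unadjusted p under 0.05.

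**Figure D3:**
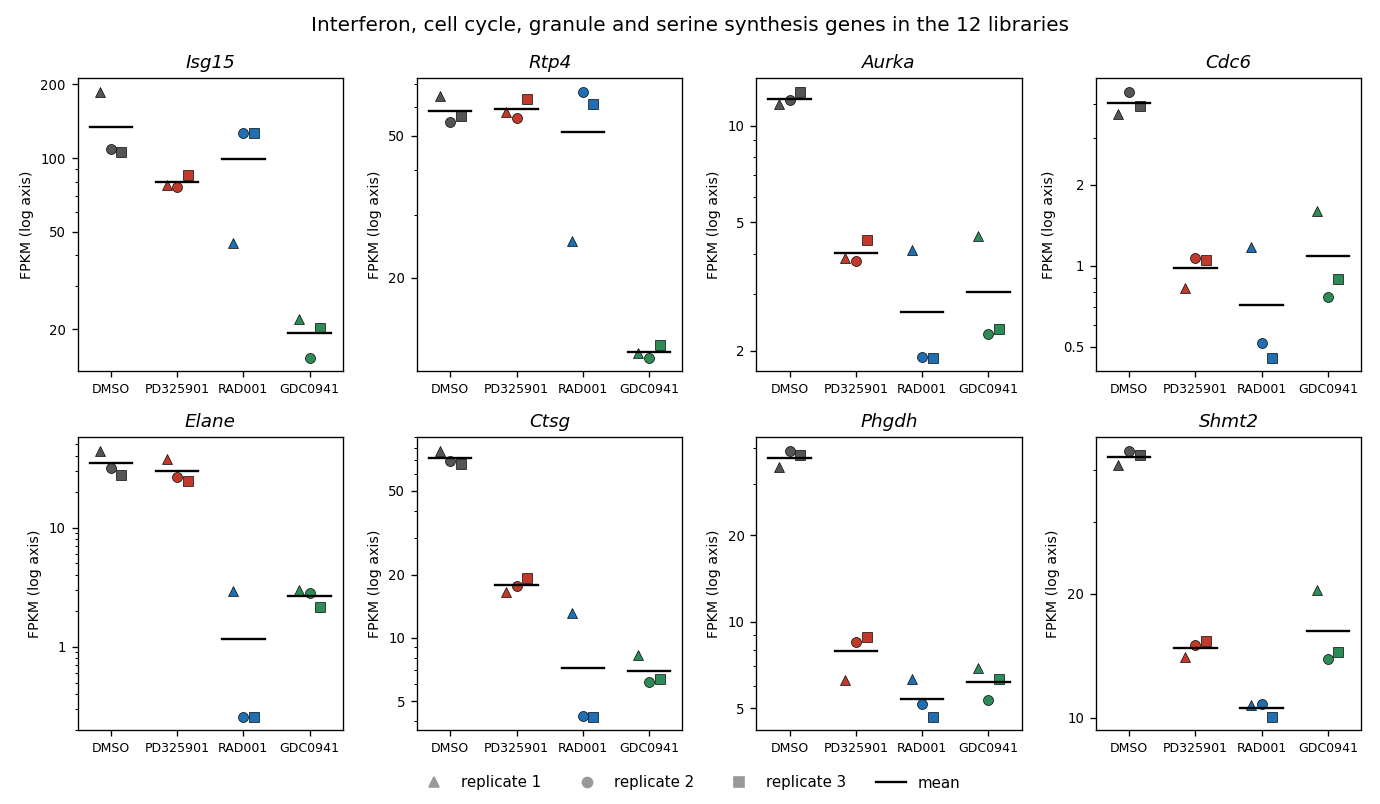
FPKM of 8 genes in the 12 libraries by group, on a log axis (points are libraries, black lines are group means). Isg15 and Rtp4 lie lowest with GDC0941, Elane and Ctsg are low with RAD001 and GDC0941, and Aurka, Cdc6, Phgdh and Shmt2 are below DMSO with each inhibitor.

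The inhibitors were compared with each other to test which effects differ between the MEK, mTOR and PI3 kinase inhibitors at these doses. PD325901 differed from GDC0941 in ribosome biogenesis, ERK output, interferon response and primary granule genes. Mmp12 was 4.41 ± 0.501 against 3808 ± 468 FPKM (log2 difference -9.46 ± 0.21, adjusted p = 2.79e-10 by limma), and Mmp13 (-6.10 ± 0.26), Ccl7 (-6.64 ± 0.58) and Ccl2 (-6.36 ± 0.32) were lower with PD325901. The neutrophil granule protein lactoferrin, Ltf (4.21 ± 0.74), Ifit3 (3.75 ± 0.43), Acp5 (3.99 ± 0.27) and Tmem37 (3.66 ± 0.21) were higher with PD325901. ERK output genes were lower in 19 of 23 (median log2 change -2.64, adjusted p = 4.6e-08, adjusted p = 0.195 with an estimated correlation) and ribosome biogenesis genes in 30 of 30 (median log2 change -1.23, adjusted p = 7.16e-15, adjusted p = 0.332 with an estimated correlation), by limma camera. Interferon response genes were higher with PD325901 in 24 of 26 and lower in 1 (median log2 change 1.45, adjusted p = 1.25e-08, adjusted p = 0.591 with an estimated correlation), and primary granule genes were higher in 12 of 13 (median log2 change 1.98, adjusted p = 1.75e-06, adjusted p = 0.177 with an estimated correlation). Adjusted over the list alone these counts were 19, 30, 25 with 1, and 12. Across all genes, 5312 of 10305 differed, 2150 higher and 3162 lower with PD325901, 1269 of them by at least 1 on the log2 scale (635 higher and 634 lower). Psap was listed at 0 with PD325901 and at 3855, 5821, 6377 FPKM with GDC0941.

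PD325901 and RAD001 differed in ERK output genes, in the NF-kB, cytokine and chemokine list and in other lists. Beyond those described below, mitosis (adjusted p = 0.000165), lysosome and TFEB targets (0.0177) and antigen presentation (0.0456) were higher with PD325901 by limma camera. ER stress genes were lower (0.000155). None of these passed with an estimated correlation. Mmp12 was 4.41 ± 0.501 against 3379.8 ± 438 FPKM (log2 difference -9.28 ± 0.21, adjusted p = 2.28e-10 by limma), and Cxcl3 (-9.81 ± 0.47), Serpinb2 (-9.89 ± 0.32) and Mmp13 (-8.95 ± 0.26) were lower with PD325901. Fabp3 (4.88 ± 0.24), Fabp4 (5.14 ± 0.69), Cbr2 (4.82 ± 0.28) and Klk1b11 (5.61 ± 0.44) were higher. ERK output genes were lower with PD325901 in 20 of 23, or 21 adjusted over the list alone (median log2 change -2.43, adjusted p = 2.03e-10, adjusted p = 0.177 with an estimated correlation), NF-kB, cytokine and chemokine genes in 18 of 25, also 18 adjusted over the list alone, and higher in 2 (median log2 change -1.32, adjusted p = 0.000155, adjusted p = 0.591 with an estimated correlation). Ribosome biogenesis genes were lower in 30 of 30, also 30 adjusted over the list alone (median log2 change -1.03, adjusted p = 4.06e-13, adjusted p = 0.332 with an estimated correlation), while primary granule genes were higher in 10 of 13, or 12 adjusted over the list alone (median log2 change 1.64, adjusted p = 2.42e-06, adjusted p = 0.177 with an estimated correlation), by limma camera. Across all genes, 5172 of 10305 differed, 2145 higher and 3027 lower with PD325901, 1211 of them by at least 1 on the log2 scale (518 higher and 693 lower). After quantile normalization 2639 were higher and 2572 lower. Fth1 was listed at 0 with RAD001 and at 17047, 12011, 13051 FPKM with PD325901, and Psap at 0 with PD325901 and 2480.0, 4120.4, 4026 FPKM with RAD001.

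GDC0941 and RAD001 differed least. Beyond the lists described below, ribosome biogenesis (adjusted p = 0.000187), fatty acid synthesis (0.00456) and mitosis (0.0272) were higher with GDC0941 by limma camera. Antigen presentation (2.85e-05), the NF-kB, cytokine and chemokine list (0.000246) and stem and progenitor genes (0.0177) were lower. None of these passed with an estimated correlation. Ppbp was 0.615 ± 0.0961 against 183 ± 16.8 FPKM (log2 difference -6.83 ± 0.22, adjusted p = 1.88e-08 by limma), Serpinb2 17.4 ± 6.81 against 1551 ± 105 FPKM and Pf4 4.08 ± 0.590 against 241 ± 32.7 FPKM, all lower with GDC0941, as were Cxcl3 (-6.28 ± 0.47) and Ly6a (-4.47 ± 0.50). Car4 (3.61 ± 0.30), the vesicle protein Syngr1 (2.57 ± 0.20), Fabp4 (3.16 ± 0.69) and Klk1b11 (2.59 ± 0.44) were higher with GDC0941. Fabp4 varied with GDC0941, at a mean of 84.0 ± 99.3 FPKM, and did not pass with only the 2 groups compared (adjusted p = 0.0633). Sterol synthesis genes were higher with GDC0941 in 15 of 23, or 20 adjusted over the list alone (median log2 change 0.91, adjusted p = 4.88e-10, adjusted p = 0.583 with an estimated correlation). By replicate number the sterol medians were 1.20, 0.73 and 0.81. Interferon response genes were lower in 22 of 26, or 26 adjusted over the list alone (median log2 change -1.13, adjusted p = 1.45e-12, adjusted p = 0.440 with an estimated correlation), and neutrophil maturation markers in 12 of 23 with 1 higher, or 15 and 1 adjusted over the list alone (median log2 change -1.14, adjusted p = 6.73e-09, adjusted p = 0.332 with an estimated correlation), by limma camera. The interferon medians by replicate number were -0.37, -1.43 and -1.36. ERK output genes were lower in 6 and higher in 1 of 23, or 11 and 1 adjusted over the list alone (median log2 change -0.37, adjusted p = 0.00237, adjusted p = 0.440 with an estimated correlation), with medians of -0.52, -0.44 and -0.09 by replicate number. Across all genes, 1798 of 10305 differed, 834 higher and 964 lower with GDC0941, 327 of them by at least 1 on the log2 scale (74 higher and 253 lower). That count was 960 without RAD001 replicate 2 and 967 without RAD001 replicate 3, 3413 without the replicate 1 library of every group, 3048 with library weights and 695 with only the 2 groups compared. After quantile normalization 1152 were higher and 906 lower. Fth1 was listed at 0 with RAD001 and at 23090.2, 20293, 23356 FPKM with GDC0941.

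RAD001 and GDC0941 changed many genes in the same direction, while PD325901 shared fewer. Among called genes 648 rose and 732 fell with both RAD001 and GDC0941 and 65 went opposite ways, where independent calls would give 184, 208 and 391. PD325901 and RAD001 shared 452 rises and 742 falls with 605 opposite, where independent calls would give 291, 462 and 749. PD325901 and GDC0941 shared 341 rises and 509 falls with 577 opposite, where independent calls would give 219, 369.5 and 578. These values for independent calls leave out the shared DMSO libraries, whose deviations push calls in the same direction. The excess of shared calls is therefore not a measure of shared drug effects alone. The log2 changes correlated across genes, which are not independent replicates, with Pearson r = 0.602 and Spearman rho = 0.593 for RAD001 and GDC0941, 0.0948 and 0.180 for PD325901 and RAD001, and 0.103 and 0.117 for PD325901 and GDC0941. All 3 comparisons use the same DMSO libraries, and unchanged groups simulated against shared controls had a Pearson r of 0.501 from the controls alone. The covariance, to which the simulated controls added 0.0154, was 0.172 for RAD001 and GDC0941, 0.0342 for PD325901 and RAD001 and 0.0332 for PD325901 and GDC0941. The Pearson r for PD325901 and RAD001 was 0.165 without RAD001 replicate 1, 0.0489 without RAD001 replicate 3, 0.188 without the replicate 1 library of every group and 0.0461 with a filter at 5 FPKM. For PD325901 and GDC0941 it was 0.186, 0.0505 and 0.0558 without GDC0941 replicates 1, 2 and 3, 0.169 without the replicate 1 library of every group and 0.0472 with that filter.

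Of 15 T and NK cell markers 2 were tested, Cd3d and Cd28, and the median of the marker means was 0.288 FPKM with DMSO, 0.626 with PD325901, 0.204 with RAD001 and 0.110 with GDC0941. Cd28 fell with GDC0941 from 9.49 ± 2.18 to 1.44 ± 0.565 FPKM (log2 change -2.11 ± 0.25, adjusted p = 0.000313) by limma and was lower with RAD001 (-1.30 ± 0.25), and Cd3d was higher with PD325901 (1.27 ± 0.35, adjusted p = 0.0106), though not with a pseudocount of 0.1 (adjusted p = 0.102). B cell markers had medians of 0.0394, 0.121, 0.0401 and 0.0159 FPKM in the same order, and Cd22 was higher with PD325901 (1.58 ± 0.17), RAD001 (1.14 ± 0.17) and GDC0941 (1.55 ± 0.17) while Cd79b, at 5.03 ± 0.759 FPKM with DMSO, was lower with RAD001 (-1.39 ± 0.23) and GDC0941 (-1.49 ± 0.23). Of 12 erythroid markers found none was tested, and the highest, Hba-a1, whose copies are near-identical, had a mean of 1.55 FPKM with PD325901. Of 9 megakaryocyte markers Pf4 changed with PD325901 (-2.50 ± 0.37), RAD001 (1.35 ± 0.37) and GDC0941 (-4.23 ± 0.37), and Ppbp fell with PD325901 (-1.64 ± 0.22) and GDC0941 (-1.69 ± 0.22). The Pf4 rise with RAD001 did not pass without DMSO replicate 2 or 3 (adjusted p = 0.0635 and 0.0678). Of 12 stromal and endothelial markers 1 was tested, Pecam1, which myeloid cells also express and which fell with PD325901 (-0.65 ± 0.15), RAD001 (-0.85 ± 0.15) and GDC0941 (-2.31 ± 0.15). The mast cell, basophil and eosinophil list did not pass with PD325901 (adjusted p = 0.876) or RAD001 (0.171), with Cpa3 and Ear2, which has near-identical relatives, changed by -3.33 ± 0.69 and 2.26 ± 0.32 with PD325901.

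The replicate 1 libraries differed from the others in every group. Cd3e, Cd3g and Lck, which are T cell genes, were near 0 in them, with Cd3g at 0.0694, 1.71 and 1.48 FPKM in DMSO replicates 1, 2 and 3. The interferon gamma target Cxcl9 was 0.0850, 4.07 and 4.31 FPKM in the same libraries. These genes were chosen after their values were seen. Of the 15 fixed T and NK cell markers 6 were lowest in replicate 1 in all 4 groups. Cd28 did not follow, and was highest in replicate 1 with PD325901 (13.9, 10.1, 10.3 FPKM). Cd3d was an exception too, at 4.40 FPKM in PD325901 replicate 1. Of the 10305 genes tested 554 (5.38%) were lowest and 1061 (10.3%) highest in replicate 1 in all 4 groups, where independent libraries would give 1.23% each.

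**Figure D4:**
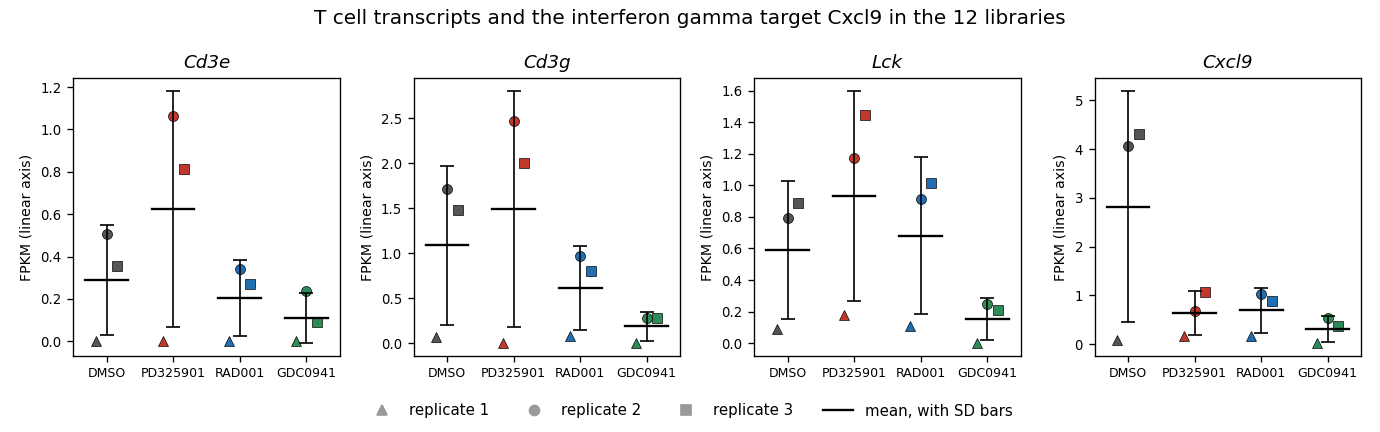
FPKM of the T cell genes Cd3e, Cd3g and Lck and of Cxcl9 in the 12 libraries by group on linear axes (points are libraries, black lines are means and bars are SD, n = 3). Replicate 1, drawn as a triangle, is the lowest library in every group. The genes were chosen after their values were seen, and 6 of the 15 fixed T and NK cell markers were lowest in replicate 1 in all 4 groups.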

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

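The comparisons, lists, tests and alternatives were chosen before the data were examined, except for the alternatives said above to be added later. The direction and the side of the threshold of named genes stayed as reported in 2174 cases when 1 library was left out, while 90 lost the call and 2 gained it, and for lists the numbers were 413, 9 and 10. In the other settings, named genes lost their call most often with only the 2 groups compared (13). The cause was not tested for any change given here, except that a minimum on the change lowers a count by construction. Depth limits what can be said of genes under 1 FPKM, which were not tested, and FPKM without counts gives no counting error.

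With a log2 change of at least 1 required, the counts were 905, 649 and 589 for PD325901, RAD001 and GDC0941 against DMSO, 1269 for PD325901 against GDC0941, 1211 for PD325901 against RAD001 and 327 for GDC0941 against RAD001, in place of 4802, 3224, 2503, 5312, 5172 and 1798. With limma library weights they were 6923 for RAD001, 3849 for GDC0941 and 3048 for GDC0941 against RAD001. With only the 2 groups compared GDC0941 against RAD001 had 695. Without the replicate 1 library of every group GDC0941 had 4281, GDC0941 against RAD001 3413, and the correlation of PD325901 with GDC0941 was 0.169. In that setting sterol synthesis genes with GDC0941 turned from a test upward to a call downward (unadjusted p = 0.000398 and adjusted p = 0.000989 by limma camera over all genes). With the other settings that kept all libraries, counts stayed within 1.5 times those reported. The majority of changes turned upward with quantile normalization for PD325901, GDC0941, PD325901 against RAD001 and GDC0941 against RAD001, as given above. The same held with a filter at 5 FPKM for RAD001 and GDC0941 and with median-ratio scaling or library weights for RAD001.

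With the replicate block in the model the counts were 5241, 3712 and 2956 against DMSO and 5617, 5572 and 2307 between inhibitors, in the order given above, and the ribosome biogenesis call with RAD001 ended (adjusted p = 0.0713 by limma camera). With an estimated inter-gene correlation 0 lists passed for PD325901, RAD001 and GDC0941 by limma camera, with or without the block, in place of 12, 13 and 12. The smallest adjusted p were 0.164, 0.141 and 0.141, and 2, 4 and 4 lists had an unadjusted p under 0.05.

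Leaving out each library in turn gave 4016 to 4247 genes for PD325901, 2216 to 3250 for RAD001, and 1632 (without DMSO replicate 2) to 3131 (without GDC0941 replicate 1) for GDC0941. It gave 4518 to 5142 for PD325901 against GDC0941, 4395 to 4819 for PD325901 against RAD001, and 960 (without RAD001 replicate 2; 967 without RAD001 replicate 3) to 1975 (without RAD001 replicate 1) for GDC0941 against RAD001. Lists past the threshold ranged from 12 to 13, 12 to 15 and 10 to 13 for the 3 inhibitors. The correlations ranged from 0.0489 to 0.165 for PD325901 with RAD001, 0.0505 (without GDC0941 replicate 2) to 0.186 (without GDC0941 replicate 1) for PD325901 with GDC0941, and 0.567 to 0.631 for RAD001 with GDC0941.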

Other observations

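The chance splits were planned. The tests of the 3 patterns below were chosen after the result was seen, and 1 bound was changed after a first result, as stated there.

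Replicate 1 differed in more than some T cell transcripts. Of the mast cell and basophil genes, Cpa3 was 139 FPKM in DMSO replicate 1 against 16.9 and 14.9 in replicates 2 and 3, and Hdc, the histidine decarboxylase, was 57.2 against 19.4 and 19.0. Hdc was chosen after its values were seen. Of 32 lysosome and TFEB targets 12 were highest and 1 lowest in replicate 1 in all 4 groups, of 25 glycolysis and hypoxia genes 12 were highest, and of 25 NF-kB targets, cytokines and chemokines 8 were highest. Of 24 antigen presentation genes 7 were lowest and 1 highest, and of 27 interferon response genes 5 were lowest. No biological explanation was tested for these, since no label separates replicate 1.

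With 10 splits of 6 libraries into 3 and 3, a share under 0.05 is impossible, and the real split, 1 of 10, had the most genes in each of the 6 comparisons. With the other libraries kept, the real split had the counts given above by limma. The highest other split had 1, 4 and 0 genes for PD325901, RAD001 and GDC0941 against DMSO and 0 between inhibitors. Every other split puts libraries of both conditions in each group, so treatment effects widen the spread. Low counts there follow from this design, and nothing is concluded from them.

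Interferon response genes were lower with GDC0941 than with DMSO, with a list median of -1.48. In the replicate 1, 2 and 3 pairs it was -1.55, -1.45 and -1.32. Interferon gamma from T cells is a candidate explanation, since the median of the T and NK marker means was 0.110 FPKM with GDC0941 and 0.288 with DMSO. With PD325901 that marker median was higher, at 0.626 FPKM, while the interferon list median was 0.02. The replicate 1 libraries of the other groups, where Cd3e was listed at 0, lay above the GDC0941 mean by list medians of 1.52 (DMSO), 1.29 (PD325901) and 0.30 (RAD001), where no GDC0941 library deviated by more than 0.08. This counts against loss of T cells as the whole cause only if those libraries lacked T cells, which is undecided below. Cxcl9, Gbp2 and Iigp1, which interferon gamma induces, were lower in replicate 1 of every group, so this explanation stays open. Those genes were chosen after their values were seen. Scaling is argued against by medians of -1.48 after median-ratio scaling and -1.50 after quantile normalization, and no other explanation was tested.

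The T cell transcripts Cd3e, Cd3g and Lck were near 0 in the replicate 1 library of every group. T cells among the cells of replicates 2 and 3 may explain this, and 6 of 15 fixed markers were lowest in replicate 1 in all 4 groups, as were 3.68% of 2282 genes at the same low level. This fell between the bounds set (at least 50% of them, or no more than 2 of them), so it stays undecided. The most abundant marker, Cd28, did not follow and was highest in replicate 1 with PD325901 (13.9, 10.1 and 10.3 FPKM), nor did Cd3d with PD325901, and no label names a sort that would remove T cells. Fewer reads in replicate 1 are argued against, since those 2282 genes had a median replicate 1 difference of 0.0854 against -0.71 for the markers.

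Interferon response genes were below DMSO in RAD001 replicate 1 and not in the other RAD001 libraries, with list medians of -1.04, 0.30 and 0.27 in the 3 pairs. A GDC0941 library under that label could give this. At genes that part the 2 drugs by at least 1 on the log2 scale, 71.3% of 411 lay nearer RAD001. This missed the bound of 80% and left the question undecided. The bound on the genes was then raised to 3 after that result was seen, and 100% of 16 genes lay nearer RAD001. A bound moved in this way, on so few genes, cannot decide the question. Of the GDC0941 replicate 1 values 83.0% and 93.8% lay nearer GDC0941 at the same 2 bounds. Spearman correlations of RAD001 replicate 1 were 0.973 and 0.971 with the other RAD001 libraries and 0.949 to 0.958 with the GDC0941 libraries. These correlations argue against a GDC0941 library under that label. Scaling is argued against by a median over all genes of 0.00339, so a difference in that 1 culture or library stays open, and no biological explanation was tested.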
